A study of Apis cerana with 76 samples.

How the data were processed

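The samples were small RNA libraries of wild-type Apis cerana. Per the labels, organs were dissected and flash frozen, total RNA was taken with Trizol, and 1 ug went into a small RNA kit for Illumina sequencing. There were 54 stage libraries (18 groups of 3) and 22 organ libraries (11 groups of 2), with 51-base reads.

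The deposited count tables held miRNA read counts that the authors had summarised to 1 column per group, with 146 entries over 18 stage groups and 171 entries over 11 organ groups. The total of the DRB column exceeded the reads of its largest library, and those of 5 stage columns, DRB among them, exceeded the mean reads of their libraries, so these cannot be means. For the other columns sum and mean were not separated; shares of reads treat every column as a sum. The authors' sequencing statistics gave total read counts and GC content in percent for each of the 76 libraries, and these were joined to the groups by the group names. The authors' lists gave 200 conserved miRNAs and a list of 13 further miRNAs of 21 to 23 bases, with lengths in bases. Of the 13, 0 were in the count tables. Of the names counted, 130 of 145 in stages and 168 of 170 in organs were in the conserved list, so some named entries may be outside it. The submitters' processing notes name bcl2fastq and kallisto without versions; other settings and a genome build were not given in the sources used here. Of 99 entries present in both tables, 37 had a different sequence in each, and 11 organ entries shared a sequence with another entry, so levels were not compared between the tables. The set of egg-abundant miRNAs used below was, however, matched to organ entries by name alone. In organs, miR-2a-2-5p, miR-2a-3-3p and miR-2a-5p are 3 entries of 1 sequence, and the growth and apoptosis list and the mir-71/mir-2 cluster count each of them. miR-3786-3p and miR-6000-3p each share their sequence with 1 other entry.

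The comparisons, the lists, the naming rule and the alternatives were fixed before the data were examined, except where an alternative is said to be added later. They had been planned for single libraries, but the tables pool each group, so each pooled column became 1 unit. The p-values therefore measure the spread between stage or organ columns, not between replicate libraries. Counting intervals and the floor of 3 counts cover counting error alone. The plan for each series was 1 fit of all its libraries with 1 mean per group and no other term. The class means, the separate fit of queen pupae with a term for the code, and the drone term for organs described below were not in that plan.

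Counts were scaled by trimmed mean of M-values (TMM) and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, after filterByExpr with a minimum count of 10. Calls had a Benjamini-Hochberg adjusted p of at most 0.05. Pupae against larvae and adult workers against pupae came from 1 fit of class means over 18 columns, with 10 residual degrees of freedom. Queen pupae against pupae used 6 columns with a term for the code. Brain against gut, ventriculus against rectum and drone against worker organs used 11 columns with organ class and a drone term. The last 4 comparisons had 2 residual degrees of freedom each.

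The other 10 comparisons had 1 column on a side. For these the log2 ratio was the difference of mean log2 of CPM plus 1. A miRNA was counted when it was at least 2-fold apart, lay outside the range of the other side, and had at least 50 CPM on its higher side. A miRNA with 0 counts on a side was given as a bound on the TMM-scaled level against 3 counts summed over that side, and 1 to 3 counts carry an exact binomial 95% interval. Testis, mucus gland and venom gland were each set against brain, ventriculus and rectum of the same kind of bee, as planned, so that the remaining organ of that bee was not used there. As an alternative added after the data were seen, edgeR was also fitted to the comparisons of 1 column against several, assuming that the lone column varies like the others (pooled spread).

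The named miRNAs were up to 10 in each direction by size among those called with a mean of at least 50 CPM on the higher side, in tested comparisons too, the members of the lists, and the 5 with the highest mean share; for the untested comparisons the text stops earlier in the order of size. Other miRNAs set beside them, such as miR-34-5p in larvae, were list members. The 10 lists were the let-7 complex, neural, muscle, gut and excretory, ovary and germline, Hox cluster, ecdysone and juvenile hormone, growth and apoptosis, mir-71/mir-2 cluster and early embryo; some miRNAs are in more than 1 list. Lists with at least 3 members were tested with fry of limma 3.58.1, which asks whether members move on balance one way, with adjustment over lists and comparisons within a table.

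Simulated data with 30 changed miRNAs in 20 runs per comparison were used to check the tests. Of 2-fold and 8-fold changes, 9.38% and 93.9% were recovered for pupae against larvae, 4.06% and 65.4% for adult workers against pupae, and 8.75% and 83.9% for queen pupae. The corresponding shares were 2.81% and 41.1% for brain against gut, 0.938% and 17.5% for ventriculus against rectum, and 1.56% and 31.8% for drone against worker organs. False calls made up 1.89% to 5.34% of calls. The counts were drawn from 1 mean profile shared by all columns, with the trended spread of the fit and about as many rises as falls. Spread particular to single miRNAs or columns was not simulated, so these shares hold for that setting alone.

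Alternatives were DESeq2 1.42.0, its size factors in edgeR or in the ratios, library totals, no filter, only the compared columns, and limma-trend on the columns. Added after the data were seen were limma-trend for the organ comparisons, leaving out each column or pair, pseudocounts of 0.1 and 10 CPM, no minimum level, entries with the same sequence collapsed, and bounds with a column left out or on the mean of columns. For ratios, leaving out a column of the side with several can narrow its range, so more miRNAs may meet the criteria for that alone. Tables and figures used Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Tests among all 18 stage groups or 11 organ groups, of whether the drone effect differs between organs, and of replicate terms were not run, because each pooled column would need its own term and no residual degrees of freedom would remain. Added after the data were seen, edgeR tested differences among 8 stage classes (10 residual degrees of freedom), among 8 organ classes (2), between the queen effects in adults and pupae (10) and among the queen effects in W, R and DR pupae (5), with lone columns assumed to vary like the others.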

Results

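Small RNAs of the Asian honey bee, Apis cerana, were sequenced in 76 libraries, to profile miRNAs across its development and its organs. The stage series held 54 libraries in 18 groups of 3. It covered egg (E), larvae (L1 to L5), pupae (W, R, DR and DRB), adult workers (YA and OA), adult drones (D), queen larvae (QL), queen pupae (QW, QR and QDR) and adult queens (QA). The organ series held 22 libraries in 11 groups of 2. It covered brain, ventriculus (the midgut) and rectum of workers and of drones, worker ovary, worker venom gland, drone testis, drone mucus gland and queen ovary. The labels give no caste for the plain larvae and pupae. The count tables held 1 column per group, in which the authors had pooled its libraries, so every level given here is a pooled value of the authors with no replicate error within a group.

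Libraries held 3.34 to 42.4 M reads in the stage series and 8.71 to 14.9 M in the organ series. Summed miRNA counts ran from 72873 in adult queens to 19772824 in DRB pupae, and from 184457 in worker rectum to 8476499 in drone mucus gland. As a share of sequenced reads, with each column taken as the sum of its libraries, miRNA counts made up 0.213% in adult queens, 0.503% in egg, 2.32% in queen larvae, 1.79% in QW and 2.12% in QR pupae. The same share was 44.4% in QDR pupae, and 21.98%, 30.2% and 57.1% in W, R and DR pupae. In 5 of 18 stage columns (DR, DRB and QDR pupae, YA workers and adult drones) the counts exceeded the mean reads of the libraries, so these cannot be means. Any other column that holds a mean has a share 3 times as high (2 times in organs), which for adult queens would be 0.639%, for QW 5.36% and for QR 6.36%. A level of 3 counts, taken as the detection floor, was 41.2 CPM (counts scaled to a common column total) in adult queens and 0.152 CPM in DRB pupae, before scaling. In both series miR-184-3p, which acts in the germline and in early development of flies, had the highest mean share, 31.7% of counts over stages (12.3% to 46.8%) and 33.7% over organs (12.4% to 67.3%). It was not first in every column: miR-1-3p was first in YA and OA workers, adult drones, both rectum columns and mucus gland, and miR-8-3p in queen larvae. By mean share it was followed over stages by miR-8-3p (18.3%), the muscle miRNA miR-1-3p (14.5%), let-7-5p (5.69%) and miR-9-5p (5.22%), and over organs by miR-1-3p (13.7%), miR-276-3p (5.10%), miR-31a-5p (4.14%) and let-7-5p (3.53%). With columns grouped into classes, edgeR called 96 of 145 miRNAs as differing among 8 stage classes and 59 of 135 among 8 organ classes, in tests chosen after the data were seen.

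**Figure D1:**
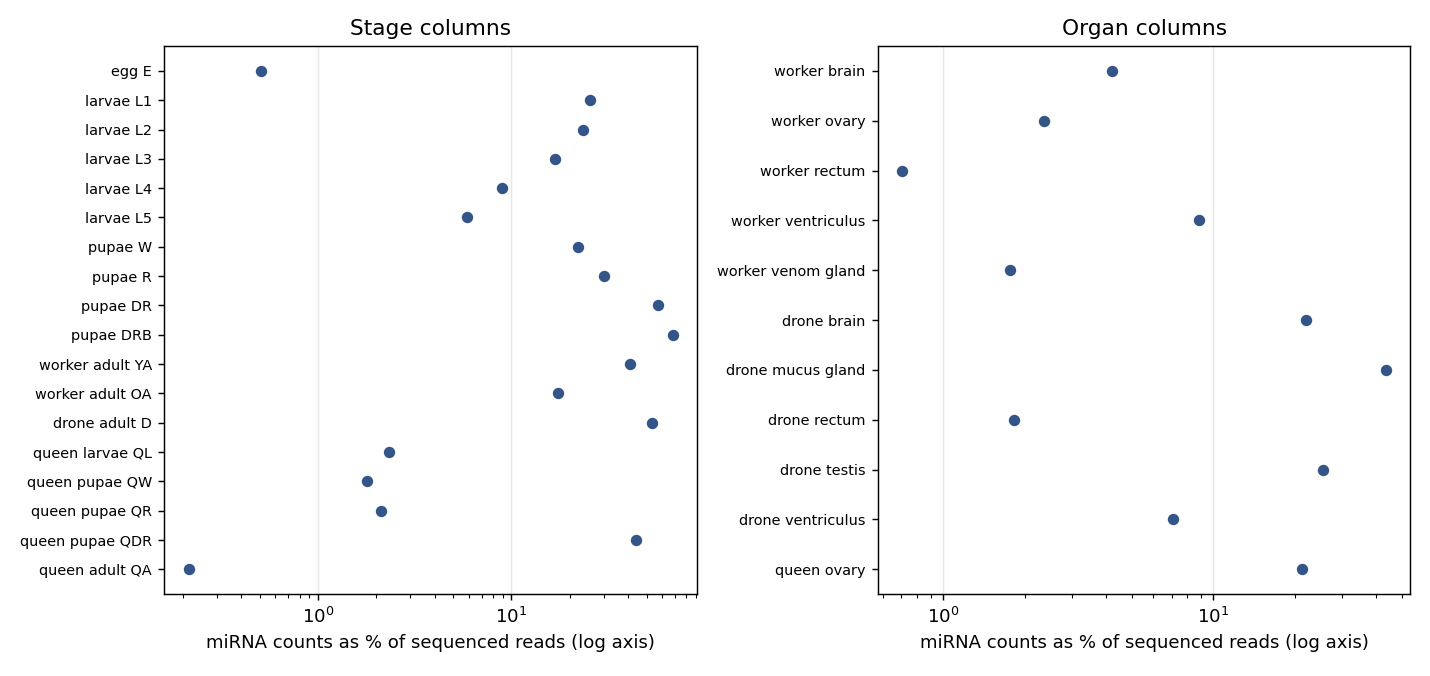
Summed miRNA counts as a percentage of sequenced reads (log axis) in each pooled column, taken as a sum of libraries, 1 point per column, for 18 stage groups and 11 organ groups. Adult queens were lowest among stages at 0.213% and DRB pupae highest at 68.5%, and organs ran from 0.704% in worker rectum to 43.7% in drone mucus gland.

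Larvae were set against egg for the opening step of development. Of the gut and excretory list, 5 of 7 measured members were higher in larvae with TMM, 3 with DESeq2 size factors and 2 with library totals, and none was lower under any of these. Among them were miR-275-5p, with a log2 ratio of 4.01 (2551 against 156 CPM), and miR-1175-3p, at 58.5 CPM against 3 counts in egg (95% counting interval of the log2 ratio of summed counts 1.78 to 5.61). Over all miRNAs, the summed larval counts of miR-2478 were at least 20.5-fold above the floor of 3 counts in egg, or 18.8-fold for the mean of the larval columns (35.5 to 180 CPM), followed by miR-3968 at a log2 ratio of 5.10 (885 against 21.5 CPM). miR-3478-3p was lowest against egg, at -9.02 (4.36 against 2529.7 CPM), followed by miR-3791-3p at -7.66 (12.3 against 2651 CPM), miR-2944-3p at -7.45 (259.6 against 26337 CPM) and miR-279b-3p at -6.63 (152 against 10911 CPM). The let-7 complex had 2 of 3 measured members higher, but 1 with DESeq2 size factors and 0 with library totals. The ovary and germline list had 2 of 7 higher and 4 lower and the Hox cluster 1 of 3 higher and 2 lower, and with library totals these had 0 higher. The mir-71/mir-2 cluster had 3 of 6 lower, 4 with DESeq2 size factors and, of its 8 members, 7 with library totals. None of the 2 muscle miRNAs met the criteria, and 1 of 4 neural and 1 of 4 early embryo members were lower, although the median log2 ratio of the neural and the early embryo list was above 0 and the mean under it. With DESeq2 size factors 2 neural and 2 early embryo members were lower, and with library totals 3 neural, 2 early embryo and 1 muscle. The ecdysone and juvenile hormone list had 5 of 8 higher and 1 lower, and the growth and apoptosis list 3 of 9 higher and 2 lower; with library totals these became 1 higher and 2 lower, and 1 higher and 6 lower. Of 88 miRNAs at 50 CPM or more, 51 were at least 2-fold apart and outside the larval range, 28 higher and 23 lower. In all, 61 of the 88 lay outside the range, which chance gives a lone column against 5 in 33.3% of orders. The difference was not tested, because egg had 1 column. With the spread pooled over the other groups, edgeR called 23 of 145, 7 higher and 16 lower. The split depended on the scaling: 17 higher and 29 lower with DESeq2 size factors, and 9 higher and 42 lower with library totals, which moved the median log2 ratio by -1.18.

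Pupae were set against larvae for the onset of metamorphosis. let-7-5p, a timer of insect metamorphosis, rose from a mean of 19780.1 CPM over 5 larval columns to 107357 CPM over 4 pupal columns, a log2 change of 2.44 (SE 0.56, adjusted p 0.00490). Among miRNAs of at least 50 CPM on their higher side, the largest rises were those of miR-210-3p, at 3.44 (SE 0.64, adjusted p 0.00162), miR-927a-3p at 3.01 and miR-193-3p at 2.87; miR-2796-3p, miR-2788-5p, miR-3715-5p, miR-927b-5p, the muscle miRNA miR-1-3p and miR-87a-3p rose by 2.40 to 1.82. Within the same limit the largest falls were those of miR-2916, at -8.78 (SE 1.19, adjusted p 0.000443), miR-166-3p at -7.41 and miR-2478 at -5.73. The name miR-166-3p is one used for a plant miRNA family. miR-2944-3p, miR-750-3p, miR-3968, miR-281-3p, miR-375-3p, miR-33-3p and miR-92b-3p fell, with log2 changes of -5.29 to -2.32. Over all 145 miRNAs, pupal and larval columns did not overlap for 44, which chance gives in 1.59% of groupings; of the miRNAs named here, miR-2788-5p and miR-3715-5p overlapped.

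Among the lists, the gut and excretory group fell in pupae (fry adjusted p 0.000353), with 3 of 7 members falling and 1 rising; miR-281-3p, an insect gut miRNA, stood at 110.1 CPM against 1039. The ecdysone and juvenile hormone list fell (adjusted p 0.0012), with 5 of 9 members falling, and so did the ovary and germline list (adjusted p 0.00121), with 3 of 7 falling. The growth and apoptosis list fell (adjusted p 0.0179), with 2 of 11 falling, but not with library totals (adjusted p 0.649). The let-7 complex had 1 of 4 members rising (adjusted p 0.130; 0.0183 with library totals), and the neural list 3 of 9 rising and 2 falling (adjusted p 0.143; 0.0118 with library totals). The Hox cluster had 1 of 5 rising (adjusted p 0.967), the early embryo list 1 of 5 rising and 2 falling (adjusted p 0.306) and the mir-71/mir-2 cluster 0 of 8 passing (adjusted p 0.205); in the Hox cluster and early embryo lists the median and the mean had opposite signs. Of the 2 muscle miRNAs, 1 rose. Adjusted over the list alone these member counts were the same except for growth and apoptosis, where 1 member fell. In all, edgeR's quasi-likelihood test called 58 of 145 miRNAs, 26 rising and 32 falling. With library totals, which moved the median log2 change by 0.47, 55 were called, 37 rising and 18 falling.

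**Figure D2:**
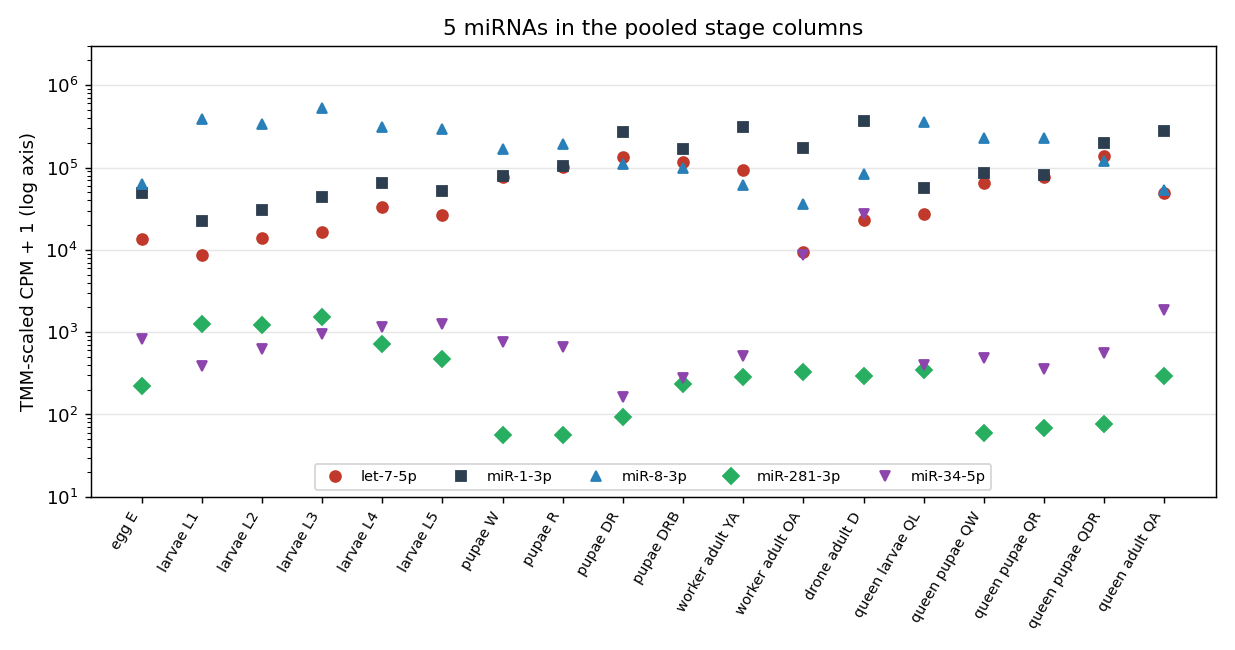
TMM-scaled CPM plus 1 (log axis) of 5 miRNAs in the 18 pooled stage columns, 1 point per column. let-7-5p stood at 8543 CPM in L1 larvae and 134822 CPM in DR pupae, while miR-281-3p stood at 1246 and 93.5 CPM.

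Adult workers were set against pupae for the completion of metamorphosis. miR-34-5p, an ecdysone-responsive miRNA linked to ageing in flies, rose by 3.31 (SE 0.84, adjusted p 0.0303) on the log2 scale, although its level was 8714 CPM in OA and 507 CPM in YA workers. miR-2944-3p rose by 6.04 (SE 1.46, adjusted p 0.0303), with 873 CPM in OA against 2.96 CPM in YA, and without OA its log2 change was -1.16. miR-277-3p rose by 3.65, miR-6057-5p by 3.26, miR-375-3p by 2.62 and miR-14-3p by 1.74. miR-3715-5p and miR-8-3p fell, with log2 changes of -4.01 and -1.53. The other 3 calls lay under 50 CPM and are named outside the rule, having been seen: miR-34-3p rose, and miR-980-3p and miR-2788-3p fell. The neural list fell (fry adjusted p 0.011; 0.0862 with library totals), although 0 of its 9 members passed over all miRNAs and 3 fell adjusted over the list alone. The Hox cluster (adjusted p 0.0165; 0 of 5 passing either way) and the early embryo list (adjusted p 0.0165, 0.2 with library totals; 0 of 5 passing, 2 falling adjusted over the list alone) also fell. The ecdysone and juvenile hormone list had 3 of 9 members rising and 1 falling (adjusted p 0.130; 0.0351 with library totals), or 4 and 2 adjusted over the list alone; growth and apoptosis had 1 of 11 rising. The other lists had no member passing over all miRNAs, and gut and excretory had 2 falling adjusted over the list alone; fry's adjusted p ran from 0.0863 to 0.321 for the lists that did not pass. Over all 145 miRNAs, adult and pupal columns did not overlap for 54, which chance gives in 13.3% of groupings; of the calls, miR-2944-3p, miR-34-5p and miR-34-3p overlapped. In all, edgeR called 11 of 145 miRNAs, 7 rising and 4 falling; DESeq2 size factors gave 10 and 2, library totals 15 and 4 with a median shift of 0.43. The count was 32 with DESeq2 and 0 with only the 6 columns compared. It rested on single columns: without OA or R it was 0, without W 6, without DR 7, without DRB 31 and without YA 39.

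The larval groups with the highest and lowest number, L5 and L1, were set side by side. miR-6001-3p was the most different, with a log2 ratio of 9.24 (17449 against 27.9 CPM), followed by miR-2765-5p at 4.82 (4182 against 147 CPM) and miR-4057 at 4.14 (1421 against 79.6 CPM). let-7-5p was higher in L5, at 26588 against 8543 CPM, and miR-34-5p at 1271 against 385 CPM. miR-2944-3p, at -4.35 (33.9 against 709 CPM), miR-279b-3p at -2.996 and miR-14-5p at -2.96 were lowest in L5 against L1. The growth and apoptosis list had 4 of 8 measured members lower and the ovary and germline list 3 of 6 lower (2 with DESeq2 size factors, 1 with library totals), with none higher in either; the ecdysone and juvenile hormone list had 2 of 8 higher and 3 lower. The let-7 complex had 1 of 3 higher, muscle 1 of 2 and early embryo 1 of 3, the neural list 1 of 4 and gut and excretory 1 of 7 each way, and the Hox cluster 1 of 2 and the mir-71/mir-2 cluster 1 of 5 lower; the neural list's median was above 0 and its mean under it. Of 81 miRNAs, 36 were at least 2-fold apart, 15 higher and 21 lower. L5 and L1 had 1 column each, so the difference was not tested. The 95% counting interval for miR-2944-3p, on 112 counts in L5, was -4.67 to -4.12.

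Within adult workers, OA was set against YA. The let-7 complex was lower in OA in all 3 measured members: let-7-5p stood at 9392 CPM against 94286 CPM, miR-125-5p at a log2 ratio of -3.20 and miR-100-5p at -2.45. miR-2944-3p, miR-3791-3p and miR-279b-3p were the most raised in OA, at 7.79 (873 against 2.96 CPM), 6.02 (448 against 5.92 CPM) and 4.71 (426 against 15.4 CPM). miR-34-5p, miR-277-3p and miR-317-3p were also higher, at log2 ratios of 4.10, 1.88 and 3.78. miR-92b-3p and miR-993-3p were lowest in OA, at -4.16 and -3.65. The mir-71/mir-2 cluster had 4 of 5 members lower, the neural list 3 of 4, the early embryo list 3 of 3 and the Hox cluster 2 of 2; gut and excretory had 3 of 7 lower and muscle 0 of 2 meeting the criteria. With DESeq2 size factors the members lower were 2, 2, 1 and 2 in the mir-71/mir-2, neural, early embryo and Hox lists, and with library totals 0, 1, 0 and 1. Gut and excretory then had 3 higher and 3 lower and muscle 1 higher, while all 3 let-7 complex members were lower under each scaling. The ovary and germline list had 1 of 6 higher and 2 lower, ecdysone and juvenile hormone 1 of 8 higher and 2 lower, and growth and apoptosis 1 of 8 higher and 4 lower. With library totals the balance of these 3 lists turned, to 2 higher and 1 lower, 4 and 1, and 2 and 1. Of 82 miRNAs, 45 were at least 2-fold apart, 13 higher and 32 lower, and with library totals 28 were higher and 19 lower, a median shift of 0.90. OA and YA had 1 column each, so the difference was not tested.

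Queen larvae were set against the 5 plain larval columns. The queen larvae carry no larval number, so caste and larval stage cannot be told apart here. miR-6497-5p, miR-6001-3p and miR-3759-3p were the most raised in queen larvae, with log2 ratios of 4.73 (373 against 24.5 CPM), 4.27 (22299 against 7449.6 CPM) and 4.02 (177 against 19.2 CPM); miR-6001-3p ran from 27.9 to 17449 CPM over the plain larvae. miR-2916, at -4.99 (5.53 against 394 CPM), miR-2944-3p at -3.22 and miR-14-5p at -3.18 (1326 against 15431 CPM) were lowest. In L5 against L1 larvae, miR-6497-5p, miR-6001-3p and miR-3759-3p were also higher, at log2 ratios of 3.24, 9.24 and 3.55. miR-2916, miR-2944-3p and miR-14-5p were also lower there, at -1.87, -4.35 and -2.96. With TMM scaling, the ecdysone and juvenile hormone list had 4 of 8 members lower, gut and excretory 4 of 7 lower and 1 higher, the mir-71/mir-2 cluster 3 of 5 lower and growth and apoptosis 3 of 8 lower. The neural list (4 members), muscle (2), ovary and germline (6) and Hox cluster (2) each had 1 lower, the let-7 complex 1 of 3 higher and early embryo 0 of 3 meeting the criteria. With DESeq2 size factors the ecdysone, mir-71/mir-2 and growth lists each had 1 lower, the let-7 complex 3 higher, early embryo 2 higher and the Hox cluster 0 meeting the criteria, and the neural, muscle and gut lists each turned to 1 higher and 0 lower, as did the neural list with library totals. Of 81 miRNAs, 34 were at least 2-fold apart and outside the larval range, 8 higher and 26 lower. In all, 51 of the 81 lay outside the range, against 33.3% by chance. This split was 16 higher and 7 lower with DESeq2 size factors and 11 higher and 14 lower with library totals, with median shifts of 0.57 and 0.34. The difference was not tested; with pooled spread edgeR called 0 of 145, with 14 at an unadjusted p under 0.05, and DESeq2 was not run. Queen larvae had 748682 miRNA counts, or 2.32% of their reads.

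Queen pupae were set against pupae of the same code (QW with W, QR with R, QDR with DR). Only miR-6497-5p, miR-3759-3p and miR-4057 passed, rising by 4.34 (SE 0.96, adjusted p 0.0259), 3.89 (SE 0.85, adjusted p 0.0259) and 2.78 (SE 0.58, adjusted p 0.0259) on the log2 scale. miR-4057 stood at 5367, 6367 and 73.3 CPM in QW, QR and QDR, against 614, 403 and 37.7 CPM in W, R and DR, so that it was higher in 3 of 3 pairs. miR-6497-5p and miR-3759-3p were also higher in 3 of 3 pairs, the latter with 1.59 against 0.890 CPM in the DR pair. The QW and QR columns had miRNA counts of 1.79% and 2.12% of reads, against 44.4% in QDR. Counted per sequenced read, the 3 miRNAs had a median log2 ratio of 0.96 in the W and R pairs, against 4.70 on the CPM scale, and miR-4057 was lower in QW than in W, at -0.79, with all columns taken as sums; were QW alone a mean, it would be higher. In the DR pair their median on the CPM scale was 0.68, and over the 3 pairs the queen and plain columns overlapped. No member of any list passed, over all miRNAs or adjusted over the list alone, and fry's adjusted p ran from 0.130 for the mir-71/mir-2 cluster (0.027 with library totals) to 0.71 for the Hox cluster. edgeR called 3 of 134 miRNAs, all rising, with 15 at an unadjusted p under 0.05 and 2 residual degrees of freedom. DESeq2 called 5, while DESeq2 size factors in edgeR, library totals and no filter each gave 0. Without the W pair 1 passed, without the R pair 0 and without the DR pair 14, of which 6 rose and 8 fell.

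Adult queens were set against the adult worker columns. The same 3 miRNAs were among the most raised: miR-4057 at a log2 ratio of 8.58 (18578 against 47.8 CPM), miR-3759-3p at 8.06 (2958 against 10.2 CPM) and miR-6497-5p at 5.80 (2467 against 44.5 CPM), beside miR-3720-5p at 7.44 (692 against 3.03 CPM). These rest on 1476, 235, 196 and 55 counts in adult queens, whose miRNA counts were 0.213% of reads. Counted per sequenced read, miR-6497-5p was lower than in YA and OA workers, at log2 ratios of -2.05 and -0.999, while miR-3759-3p stood at 0.95 and 0.74 and miR-4057 at 1.01 and 1.49. These take the adult queen column as a sum; were it a mean of 3 libraries the per-read ratios would be 3 times as high, and miR-6497-5p would lie above OA where OA is a sum. miR-927b-5p was lowest, with 3 counts in adult queens (95% counting interval of the log2 ratio of summed counts -4.93 to -1.10), followed by miR-3477-5p at -1.88 (1799.9 against 6621 CPM) and miR-92d-3p at -1.55 (214 against 649 CPM). The gut and excretory list had 3 of 6 measured members higher and 1 lower, and growth and apoptosis 3 of 8 lower; the neural list had 1 of 4 higher, or 0 higher and 1 lower with library totals. The ovary and germline list had 1 of 6 each way, ecdysone and juvenile hormone 2 of 8 lower, muscle 1 of 2 and the mir-71/mir-2 cluster 1 of 5 lower (3 of the ecdysone list, 5 of growth and apoptosis and 2 of the mir-71/mir-2 cluster lower with library totals, and 0 of the ovary list then higher), and the let-7 complex, Hox cluster and early embryo lists (3, 2 and 3 members) none, but 1 let-7 complex member higher with DESeq2 size factors and 1 early embryo member lower with library totals; the early embryo median was above 0 and its mean under it. Of 86 miRNAs, 28 were at least 2-fold apart and outside the worker range, 16 higher and 12 lower. In all, 48 of the 86 lay outside the range, which chance gives a lone column against 2 in 66.7% of orders. With library totals 12 were higher and 24 lower, a median shift of -0.38. With no minimum level 65 met the criteria, 20 higher and 45 lower. The difference was not tested; with pooled spread edgeR called 0 of 145, with 7 at an unadjusted p under 0.05, and without YA 50 met the criteria. Whether the queen effect differs between adults and pupae was tested in edgeR with the same pooled spread, and 0 of 145 passed, with 3 at an unadjusted p under 0.05; DESeq2 was not run.

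Adult drones were set against the adult worker columns. miR-34-5p, miR-210-3p, miR-317-3p and miR-277-3p were the most raised in drones, at 3.69 (27084 against 4611 CPM), 3.38 (1594 against 173 CPM), 3.21 (6071 against 1301 CPM) and 2.81 (96561 against 16767 CPM). The muscle miRNA miR-133-3p was higher at 1.86 (3749 against 1036 CPM). miR-6001-3p and the ovarian miRNA miR-989-3p were lowest, at -3.29 (23.9 against 344 CPM) and -2.37 (308 against 1604 CPM), and the ovary and germline list had 3 of 6 measured members lower and none higher. Growth and apoptosis had 3 of 8 members higher, ecdysone and juvenile hormone 2 of 8 higher and 1 lower, and the mir-71/mir-2 cluster 1 of 5 higher. With either other scaling these became 2 higher and 1 lower, 2 and 2, and 0. Muscle had 1 of 2 higher and gut and excretory 1 of 7 lower, and no member of the let-7 complex (3), neural (4), Hox cluster (2) or early embryo (3) lists met the criteria, but with library totals 2 neural, 1 Hox cluster and 1 early embryo member were lower. Of 80 miRNAs, 24 were at least 2-fold apart and outside the worker range, 16 higher and 8 lower. In all, 47 of the 80 lay outside the range, against 66.7% by chance. DESeq2 size factors gave 12 higher and 12 lower, and library totals 11 and 20, with median shifts of -0.22 and -0.48. With 1 drone column the difference was not tested; with pooled spread edgeR called 0 of 145, with 17 at an unadjusted p under 0.05, and without OA 42 met the criteria.

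Brain was set against gut (ventriculus and rectum), with worker and drone columns of each. miR-210-3p, a miRNA of nervous tissue and photoreceptors in flies, rose in brain by 7.23 (SE 0.56, adjusted p 0.00458) on the log2 scale, and miR-927b-5p by 6.81, miR-929-3p by 6.73, miR-3783-3p by 6.47 and miR-252a-5p by 6.05. miR-2796-3p rose by 6.69 (SE 0.73, adjusted p 0.00909) and reached 36711 CPM in brain. miR-2b-5p also passed, but stood at 4895 CPM in worker brain and at 0 counts in drone brain and in all 4 gut columns. In gut, miR-750-3p was higher, its log2 change for brain being -6.55 (SE 0.24, adjusted p 0.00173), as were miR-281-5p at -5.09, miR-283-5p at -4.56, miR-31a-5p at -3.69, miR-9a-5p at -3.68 and miR-12-5p at -3.35. miR-1175-3p passed as lower in brain with 0 counts in both brain columns. It also had 0 counts in worker ventriculus and worker rectum and 1 in drone rectum, so its level in gut rests on 287 counts in drone ventriculus. Its fitted log2 change turned to 2.97 without drone brain.

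The neural list had 3 of 9 members rising in brain and 1 falling (fry adjusted p 0.146; 0.0239 with 1 entry per sequence, an alternative added after the data were seen), or 4 and 1 adjusted over the list alone; miR-932-5p and miR-219-3p rose by 4.34 and 4.07. That alternative removed no neural member but moved the median log2 change by 0.52. The gut and excretory list had 3 of 6 falling (adjusted p 0.159), miR-1175-3p among them. The early embryo list fell (adjusted p 0.0183; 0.1 with library totals), with 2 of 5 members falling. Of the let-7 complex 0 of 3 passed, or 1 rising and 1 falling adjusted over the list alone; of the muscle miRNAs 1 of 2 rose, or 1 rose and 1 fell. The ovary and germline list had 1 of 7 rising, the Hox cluster 1 of 4 falling, ecdysone and juvenile hormone 1 of 6 rising and 1 falling, the same adjusted over the list alone. Growth and apoptosis (9 members) and the mir-71/mir-2 cluster (7 members), or 7 and 5 with the miR-2a sequence counted once, each had 1 rising, or 0 adjusted over the list alone. In both lists this was miR-2b-5p, which had counts in worker brain alone of the columns compared. The medians and means of both lists had opposite signs. For ecdysone and juvenile hormone both were under 0 and the test pointed up. For these remaining lists fry's adjusted p ran from 0.371 to 0.942. Over all 135 miRNAs, brain and gut columns did not overlap for 60, which chance gives in 13.3% of groupings; of the miRNAs named by size, miR-2b-5p, miR-1175-3p and miR-31a-5p overlapped. edgeR called 31 of 135 miRNAs, 18 rising and 13 falling, on 2 residual degrees of freedom, and with DESeq2 size factors 28 rose and 10 fell, a median shift of 0.47. DESeq2 called 50 and limma-trend 47. Without drone brain or worker brain 0 passed, without drone rectum 3, without worker rectum 9 and without worker ventriculus 55.

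**Figure D3:**
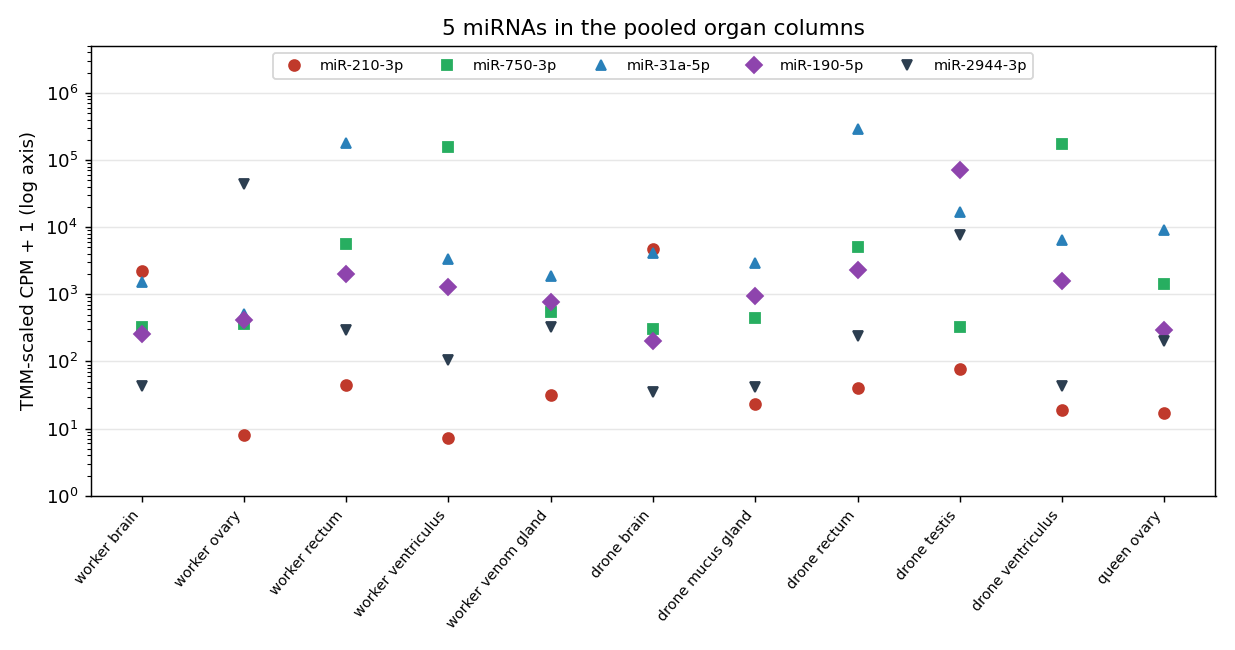
TMM-scaled CPM plus 1 (log axis) of 5 miRNAs in the 11 pooled organ columns, 1 point per column. miR-750-3p stood at 157510.0 and 175399 CPM in ventriculus, and miR-210-3p at 2225 and 4768 CPM in the worker and drone brain.

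Ventriculus was set against rectum within the gut. miR-750-3p rose in ventriculus by 4.97 (SE 0.23, adjusted p 0.00396) on the log2 scale, from 5089 to 5571 CPM in rectum to 157510.0 to 175399 CPM. miR-283-5p and miR-184-3p also rose, by 3.43 and 1.73. miR-31a-5p fell, with a log2 change of -5.61 (SE 0.31, adjusted p 0.00396) and 176587 to 292977 CPM in rectum, and so did miR-3791-3p at -3.22 and miR-276-3p at -1.21. Over all 135 miRNAs, ventriculus and rectum columns did not overlap for 78, which chance gives in 33.3% of groupings of 2 and 2. Over all miRNAs 1 list member passed, miR-184-3p of the ovary and germline list. Adjusted over the list alone, 4 of 7 rose and 1 fell in that list, 1 of 6 rose for gut and excretory and 1 of 3 for the let-7 complex, while 2 of 2 muscle, 2 of 5 early embryo and 1 of 6 ecdysone and juvenile hormone members fell. fry's adjusted p ran from 0.159 to 0.428, but with 1 entry per sequence the early embryo list passed as falling (0.0375), and for the mir-71/mir-2 cluster the median and the mean had opposite signs. edgeR called 6 of 135, with 37 at an unadjusted p under 0.05; library totals gave 3 rising and 8 falling, a median shift of -0.18. DESeq2 called 41, and with only the 4 columns compared 0 passed. Without drone rectum 3 passed, without worker rectum 3 and without worker ventriculus 16.

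Drone organs were set against the same worker organs (brain, ventriculus and rectum). With edgeR 0 of 135 miRNAs passed, with 11 at an unadjusted p under 0.05; DESeq2 called 3, and without worker ventriculus edgeR called 3. miR-184-3p, at a mean of 594888 CPM in drone and 410746 CPM in worker organs, had a log2 difference of 0.58 (SE 0.10, adjusted p 0.190), and let-7-5p 0.81 (SE 0.18, adjusted p 0.190). No list member passed over all miRNAs. Adjusted over the list alone, 2 of 6 gut and excretory and 1 of 3 let-7 complex members rose, and 1 of 7 ovary and germline members rose and 1 fell; fry's adjusted p ran from 0.159 to 0.942, but with 1 entry per sequence the early embryo list passed as falling (0.0208). The median and the mean had opposite signs for the ecdysone, growth and mir-71/mir-2 lists, and for the Hox cluster both were under 0 while the test pointed up. Library totals moved the median log2 difference by -0.50.

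Queen ovary was set against worker ovary. Among the most raised in queen ovary, miR-1175-3p had 1098142 counts there and 0 in worker ovary, a TMM-scaled level at least 146367-fold above the floor of 3 counts, where the TMM factors were 0.938 and 2.67; its count was within 0.1% of that of miR-184-3p, 1099169. miR-9889 and miR-3784 were at least 3320.4-fold and 1339.8-fold above the same floor, and the count of miR-9889, 24912, was within 0.1% of that of miR-989-3p, 24922. All 3 let-7 complex members were higher in queen ovary under each scaling, let-7-5p at 46372 against 5082 CPM. Both muscle miRNAs were higher with TMM and with DESeq2 size factors, but 0 met the criteria with library totals. miR-9c-5p, miR-6040-3p and miR-2944-3p were lowest in queen ovary, at log2 ratios of -8.28 (36.5 against 11681 CPM), -7.98 (1.12 against 536 CPM) and -7.79 (200.4 against 44574 CPM). The ovary and germline list had 4 of 7 members higher and 2 lower, the neural list 3 of 7 higher and 1 lower, and ecdysone and juvenile hormone 3 of 6 higher and 1 lower, and each turned to more lower than higher with library totals. Gut and excretory had 3 of 6 higher and 1 lower, growth and apoptosis 3 of 9 higher and 4 lower, the mir-71/mir-2 cluster 2 of 7 higher and 3 lower, the Hox cluster 1 of 2 higher and the early embryo list 1 of 4 each way, or 2 and 2, 3 and 6, 2 and 5, 1 and 1, and 1 and 3 higher and lower with library totals; the median and the mean had opposite signs for the neural, growth and mir-71/mir-2 lists. The lower members of the growth and mir-71/mir-2 lists include miR-2a-2-5p, miR-2a-3-3p and miR-2a-5p, 3 entries of 1 sequence; counted once, these lists had 3 of 7 higher and 2 lower, and 2 of 5 higher and 1 lower. Of 93 miRNAs, 68 were at least 2-fold apart, 47 higher and 21 lower; with library totals 32 were higher and 42 lower, a median shift of -1.50. With 1 column on each side the difference was not tested.

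Testis was set against drone brain, ventriculus and rectum, without the mucus gland. miR-1175-3p, miR-2b-5p and miR-2765-5p were the most raised in testis. miR-1175-3p stood at 15748 CPM against 0 to 234, and miR-2b-5p was at least 2529.9-fold above the floor of 3 counts over those 3 organs summed (749-fold without drone brain, which holds most of their counts), with 7 counts in the mucus gland. miR-2765-5p stood at 41747 CPM against 4.89 to 117; its count of 295780 was within 0.1% of that of miR-276-3p, 295633. miR-316-5p, miR-3732 and the muscle miRNA miR-1-3p were lowest, at log2 ratios of -5.80 (39.4 against 3468 CPM), -4.29 (1.69 against 143 CPM) and -4.09 (5738 against 173644 CPM). The gut and excretory list had 5 of 6 members higher, the neural list 3 of 8 higher and 2 lower, and the early embryo list 2 of 4 higher and 1 lower. Growth and apoptosis had 2 of 9 higher and 3 lower and the mir-71/mir-2 cluster 1 of 7 higher and 2 lower; with library totals each had 4 higher and 0 lower. With the 3 entries of the miR-2a sequence counted once, these became 2 of 7 each way and 1 of 5 each way. Ecdysone and juvenile hormone had 2 of 6 higher and 1 lower, muscle 1 of 2, ovary and germline 1 of 6 and the Hox cluster 1 of 2 each way, and the let-7 complex 0 of 3 meeting the criteria; the median was under 0 and the mean above it for the ovary and the growth lists. With library totals the ovary list had 3 higher and 1 lower, ecdysone 2 and 0, the Hox cluster 1 and 0 and the let-7 complex 1 and 0; with DESeq2 size factors ecdysone had 1 each way. Of 95 miRNAs, 53 were at least 2-fold apart and outside the range of those 3 organs, 37 higher and 16 lower. In all, 55 of the 95 lay outside the range, which chance gives a lone column against 3 in 50% of orders. With library totals 48 were higher and 7 lower, a median shift of 1.01. With 1 testis column the difference was not tested; with pooled spread edgeR called 31 of 135, 22 higher and 9 lower.

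Drone mucus gland was set against drone brain, ventriculus and rectum, without the testis. miR-9b-5p was the most raised, at 5128 CPM against 2 counts over those 3 organs summed (95% counting interval of the log2 ratio of summed counts 11.86 to 16.76). miR-3786-3p stood at 3415 CPM against 0 to 3131. Its sequence is shared with miR-3786-5p, which had 6703 counts in mucus gland, 13909 in drone brain, 322 in ventriculus and 215 in rectum. In ventriculus and rectum miR-3786-3p had 0 counts, so its ratio may depend on how reads were assigned to these entries. miR-iab-8-3p of the Hox cluster was at least 159-fold above the floor of 3 counts over those 3 organs summed, or 47.1-fold without drone brain. miR-9b-5p and miR-iab-8-3p also had 0 counts in testis. miR-11-3p was higher at 5.77 (16527 against 308 CPM) and the muscle miRNA miR-1-3p at 2.55 (570071 against 173644 CPM). miR-3049-5p and miR-3783-3p were lowest, at -3.67 (151 against 4914 CPM) and -3.39 (0.714 against 59.6 CPM). The Hox cluster had 2 of 3 measured members higher and 1 lower, growth and apoptosis 3 of 8 higher, the neural list 2 of 7 higher and 1 lower, and the ovary and germline list 2 of 5 lower. Muscle had 1 of 2, ecdysone and juvenile hormone 1 of 6 and the mir-71/mir-2 cluster 1 of 6 higher, early embryo 1 of 4 each way, and the let-7 complex (3) and gut and excretory (6) lists none; the neural median was under 0 and its mean above it. Of 90 miRNAs, 31 were at least 2-fold apart and outside the range of those 3 organs, 17 higher and 14 lower. In all, 36 of the 90 lay outside the range, against 50% by chance. With 1 mucus gland column the difference was not tested; with pooled spread edgeR called 7 of 135, 3 higher and 4 lower, and without drone ventriculus 47 met the criteria.

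Worker venom gland was set against worker brain, ventriculus and rectum, without the ovary. Some miRNAs higher than in those 3 organs were lower than in worker ovary: miR-2944-3p stood at 328 CPM in venom gland and 44574 CPM in ovary, and miR-9c-5p at 132 and 11681 CPM. miR-6001-5p and miR-6000-3p were the most raised, at 5.52 (160.4 against 4.27 CPM) and 3.43 (84.0 against 14.2 CPM), on 63 and 33 counts in venom gland. miR-6000b-3p, an entry of the same sequence as miR-6000-3p, had 96 counts in worker ventriculus and 0 in venom gland. miR-6000-3p had 0 counts in worker ventriculus, so its ratio may depend on how reads were assigned to these entries. miR-277-3p and the muscle miRNA miR-1-3p were higher at 2.27 (19121 against 4701 CPM) and 1.94 (286227 against 95059.9 CPM). miR-6057-5p had 0 counts in venom gland, at least 7.78-fold under its TMM-scaled level in those 3 organs summed. This rests on worker rectum, at 679 CPM: without it the bound was 2.35-fold (30.9-fold on the mean of the 3 columns, 1.95-fold without rectum), without ventriculus 15.9-fold, and brain, at 6.07 CPM, was under the venom gland's floor of 7.64 CPM. miR-7-5p of the neural list was lower at -1.93 (774 against 4329 CPM). Gut and excretory had 2 of 5 measured members lower, muscle 1 of 2 higher, and growth and apoptosis and the mir-71/mir-2 cluster 0 of 9 and 0 of 7 meeting the criteria. Ecdysone and juvenile hormone had 1 of 6 and early embryo 1 of 3 higher, the neural and the ovary lists 1 of 5 each way, and the let-7 complex (3) and Hox cluster (2) none; the early embryo median was under 0 and its mean above it. With library totals the neural list had 0 higher and 1 lower, the ovary list 0 and 1, and early embryo 0; with DESeq2 size factors the neural list had 1 higher and 0 lower and the ovary list 0 and 1. Of 85 miRNAs, 16 were at least 2-fold apart and outside the range of those 3 organs, 10 higher and 6 lower. In all, 25 of the 85 lay outside the range, against 50% by chance; library totals gave 7 and 7, a median shift of -0.14. With 1 venom gland column the difference was not tested; with pooled spread edgeR called 1 of 135, which was lower. Without worker brain 31 met the criteria and without worker rectum 28.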

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

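All of the tests of explanations in this part, the other splits of the columns and the edgeR tests of differing queen effects were chosen only after the result was seen.

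miR-989-3p moved in opposite directions in the queen pairs, with a log2 ratio of queen over plain pupae of 1.67 in the R pair and -2.08 in the DR pair. The W pair, at 1.63, moved like the R pair, and QW and QR are the columns with few miRNA counts per read. An edgeR test of the R against DR difference with pooled spread, 3.76, gave an unadjusted p of 0.00785 and an adjusted p of 0.691, so it did not pass; over the W, R and DR pairs 0 of 145 miRNAs passed, with 5 at an unadjusted p under 0.05, and DESeq2 was not run. miR-315-5p did so between organs, with a log2 ratio of drone over worker of 1.999 in ventriculus, -2.39 in rectum and -0.20 in brain; this difference was not tested. Each of these values rests on 1 column per side.

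miR-6497-5p, miR-3759-3p and miR-4057 were higher in queen than in other pupae, by a median log2 of 4.70 in the W and R pairs. The QW and QR columns hold few miRNA counts per read, and counted per sequenced read the median was 0.96 (SD 1.04, from -0.79 to 2.24), so a low miRNA yield, which may raise the share of such entries, was not excluded. These values treat all columns as sums; a mean on 1 side of a W or R pair would change its ratio by a factor of 3. In the DR pair, where both columns hold many miRNA counts, the median was 0.68, a single pair that decides nothing on caste. In the W and R pairs yield and caste cannot be told apart for these miRNAs, because those pairs differ in both. miR-4057, miR-3759-3p and miR-6497-5p were also higher in L5 than in L1 larvae, at log2 ratios of 4.14, 3.55 and 3.24. These columns carry no caste label and had miRNA counts of 5.89% and 25.6% of reads, but they differ in stage. The organ entry named miR-3759-3p was lower in queen than in worker ovary, at -4.11, with shares of reads of 21.3% and 2.36%. Whether yield was the cause was not tested there.

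The egg-abundant miRNAs of the stage series were matched to organ entries by name, without a check that their sequences were the same. Such miRNAs, miR-2944-3p among them, made up 23.4% of counts in worker ovary and 0.439% in queen ovary (7 of 10 measured in organs). They also made up 10.3% in drone testis, against at most 1.19% in the other organs, so they do not mark ovary alone. Scaling by a few abundant miRNAs moves all miRNAs of a column alike. It was argued against as the whole cause, since the median log2 of worker over queen ovary of the set, 4.07 with TMM (SD 4.07), lay 5.48 above that of the 86 other measured miRNAs (-1.41, SD 4.16), with 5 of 7 members above it; the other 2 were not. If the ovary columns were exchanged, adult queens might carry more of the egg set than workers, but its summed share there was 0.0974%, on 71 counts, against 0.140% in YA and 0.536% in OA. Of the 71 counts, 44 were miR-252b-5p and 17 miR-13a-5p, and of 14123 in YA, 8302 and 5099. miR-252b-5p was higher in queen than in worker ovary, and miR-13a-5p was not an organ entry. The order of adult queens and YA therefore says little on the other members. An exchange stays open, since whole adults and 1 column decide nothing, and a caste difference between the ovaries stays open as untested.

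In the organ columns 12 pairs of different miRNAs, each with at least 1000 counts, lay within 0.1% of each other, such as miR-1175-3p and miR-184-3p in queen ovary. From pairs within 2%, 4.45 were expected (Poisson p 0.0022, which treats pairs as independent although 3 form 1 trio in worker ventriculus); in the stage columns 11 were found against 9.35 (p 0.336). Reads shared between related sequences were argued against, since the longest stretch shared by such a pair was 6 bases. Counts entered for 2 entries when the table was made may be the source of some pairs and stay open. The organ pairs lay 1 to 14 rows apart in the authors' counts, except pairs at 99 and 127 rows, and the stage pairs 6 to 76 rows. miR-276-3p and miR-2765-5p in testis were 1 row apart. In queen ovary miR-9889 and miR-989-3p were 2 rows apart and miR-1175-3p and miR-184-3p 10. Row distance was not tested. No biological explanation was tested.

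For pupae against larvae, 1 of 100 splits drawn from the 126 of the 9 columns, the real one, gave as many calls: 58, against 36 in the highest other split. This does not exclude chance, because each stage has 1 pooled column and columns of a series of stages cannot be exchanged freely. For queen pupae 1 of 10 splits gave as many calls, the real split giving 3 and the highest other 0. These 10 splits are too few for a share under 0.05. Most of them also put both columns of a pair on the same side, although the fit kept the term for the code. Their contrast then rests on fewer pairs than the real one, so few calls could arise there. For drone against worker organs the real split gave 0 calls, so that all 10 of 10 splits, the highest other also at 0, gave as many by construction, and the count says nothing on chance.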

How the results depend on the processing

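Chosen only after the data were seen were limma-trend for the organ comparisons, leaving out columns, the pseudocounts, no minimum level, pooled spread, collapsed entries and the tests among classes or of differing queen effects. For replicate libraries, no paired analysis was possible because the columns pool the replicates and carry no replicate number, so the replicate block was not run; queen pupae were paired by code. Also not run were DESeq2, no filter and only the compared columns for comparisons with 1 column on a side, the tests among all groups, and the test of differing drone effects.

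With DESeq2, adult workers against pupae had 32 calls (11 with edgeR), queen pupae 5 (3), brain against gut 50 (31), ventriculus against rectum 41 (6) and drone against worker organs 3 (0). DESeq2 size factors gave 0 for queen pupae. Library totals gave 19 for adult workers against pupae, 0 for queen pupae and 11 for ventriculus against rectum. No filter gave 0 for queen pupae. Only the compared columns gave 0 for adult workers against pupae and 0 for ventriculus against rectum, on fewer columns. limma-trend gave 47 for brain against gut. With no minimum level 61 miRNAs met the criteria for L5 against L1, 72 for OA against YA, 65 for adult queens, 48 for adult drones, 103 for the ovaries and 37 for venom gland. Pooled spread gave 23 for larvae against egg, 0 each for queen larvae, adult queens and adult drones (14, 7 and 17 at an unadjusted p under 0.05 in edgeR), 31 for testis, 7 for mucus gland and 1 for venom gland. Tests among stage classes (93 to 97) and organ classes (59 to 68) stayed within 1.5 times with DESeq2 size factors, library totals and no filter, and those of differing queen effects in edgeR stayed at 0, with 2 to 5 at an unadjusted p under 0.05. The cause was not tested where the setting itself does not give it.

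With library totals, fry's adjusted p for pupae against larvae was 0.0183 for the let-7 complex, 0.0118 for neural and 0.649 for growth and apoptosis. It was 0.0862 for neural, 0.0351 for ecdysone and juvenile hormone and 0.200 for early embryo in adult workers against pupae, 0.0270 for the mir-71/mir-2 cluster in queen pupae, and 0.1004 for early embryo in brain against gut. With 1 entry per sequence it was 0.0239 for neural in brain against gut. For early embryo it was then 0.0375 in ventriculus against rectum and 0.0208 in drone against worker organs. No member of these lists was among the collapsed entries, and they kept 9 and 5 measured members. Collapsing did move the median log2 change, by 0.52, 0.24 and -0.15 in these comparisons. The cause was not tested further.

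Leaving out 1 column (leave-one-out) gave 0 (without OA) to 39 (without YA) calls for adult workers against pupae, 0 (without drone brain) to 55 (without worker ventriculus) for brain against gut, 3 (without drone rectum) to 16 (without worker ventriculus) for ventriculus against rectum and 0 to 3 (without worker ventriculus) for drone against worker organs. Leaving out pairs gave 0 (without the R pair) to 14 (without the DR pair) for queen pupae. Adult queens ranged from 38 (without OA) to 50 (without YA), adult drones from 34 (without YA) to 42 (without OA), mucus gland from 31 to 47 (without drone ventriculus) and venom gland from 24 to 31 (without worker brain). With all columns these had 28, 24, 31 and 16. Here leaving out a column can narrow the range that a miRNA must lie outside, so counts may rise for that alone. For adult drones, the 42 without OA were 18 higher and 24 lower. Larvae against egg (49 to 53), pupae against larvae (42 to 59), queen larvae (27 to 38) and testis (54 to 64) stayed within 1.5 times. The log2 change of miR-2944-3p in adult workers against pupae reversed to -1.16 without OA (up to 6.86, without YA), which shows that OA carried it. That of miR-1175-3p, brain vs gut, with 0 counts in both brains and both worker gut columns, reversed to 2.97 without drone brain (down to -11.65, without drone rectum).

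Of the values of named miRNAs under other settings, 901 kept their direction and threshold or moved within their interval, 191 moved further and 39 no longer passed. With 1 column left out these were 680, 6 and 127, and 2 reversed. For ratios the interval was the log2 ratio plus or minus the SD of log2 levels between the columns of the side with several. Only comparisons with 1 column on each side used the counting interval. Depth limited adult queens most, where 3 counts were 41.2 CPM.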

Other observations

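Chosen only after the data were seen were the relation of GC content with miRNA yield, the pooled-spread test and the values singled out here.

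miR-34-5p, miR-277-3p and miR-317-3p stood high in OA workers, at 8714, 26381 and 2428 CPM, and in adult drones, at 27084, 96561 and 6071 CPM. YA workers had 507, 7153 and 175 CPM. The entry miR-166-3p, a name used for a plant miRNA family, stood at 155 CPM in L3 larvae and at most 0.668 CPM in pupae. Among organs, miR-2765-5p stood at 25048 CPM in worker ventriculus and 4.89 CPM in drone ventriculus. The change of miR-166-3p from larvae to pupae passed in edgeR, at a log2 change of -7.41. For adult drones against workers edgeR with pooled spread called 0 of 145, with 17 at an unadjusted p under 0.05, and DESeq2 was not run. OA against YA and drone against worker ventriculus had 1 column on each side and were not tested.

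GC content of the reads was set against the log10 of miRNA counts as a percentage of reads, with columns taken as sums, in 2 families of 2 tests. Over 18 stage columns Pearson's r was -0.499 (permutation p 0.035, adjusted 0.07) and Spearman's rho -0.657 (permutation p 0.0036, adjusted 0.0072). Without DRB pupae and adult drones, farthest from the median GC content, r was -0.376. Over 11 organ columns r was -0.545 (permutation p 0.076, adjusted 0.076) and rho -0.600 (permutation p 0.057, adjusted 0.057). Without queen ovary and mucus gland r was -0.0721, so that Pearson's r in organs rests on those columns. Spearman's rho was not computed without them. Libraries of 1 group differed most in GC content in QDR pupae (SD 2.14), queen ovary (2.89) and mucus gland (2.33).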
